A study of Mus musculus with 96 samples.

How the data were processed

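Total RNA of kidney, brain, liver and spleen from male CBA/Ca and BALB/c mice was measured on NimbleGen MM8 mouse expression arrays with a single Cy3 label. The labels give 4 groups per tissue, namely control males and F1 males of each strain, where the F1 animals descend from a father given 1 Gy of X-rays. Each of the 16 groups held 6 males. Each sample was hybridised to 2 arrays, which are technical replicates of 1 male, so that 192 arrays gave 96 samples and n counts males. Kidney was hybridised on another version of the chip than the other tissues, and the tissues were therefore analysed apart.

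The deposited array files give, for 1 array each, a probe-level PM intensity on a linear scale, which the authors normalized by RMA per the submitters' processing notes (version not given in the sources used here). The extent of that normalization was read from the values, since arrays normalized together share 1 set of sorted intensities. All 48 brain arrays shared 1 distribution, as did all 48 liver arrays. The spleen arrays shared 1 distribution within each pair of slides (24 arrays each). The kidney arrays shared 1 distribution within each slide (12 arrays), except on slide 1, where the 3 arrays of each group had a distribution of their own, with median intensities of 405.6, 343.2, 363.6 and 317.8.

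The deposited value table of the series gives 1 log2 value per sample and target, as the authors' RMA summary. Its column medians ranged from 7.86 in liver to 9.16 in brain. The sources used here do not give how the 2 arrays of a sample were combined there or whether its columns were scaled further. When each column was correlated with the mean of 2 arrays of every sample of its tissue, after each target was centred, 48 of the 96 columns matched their own sample and 48 did not. All 48 that did not were named BALB/c control or CBA/Ca F1, and each matched the male of the same number in the other of these 2 groups. The array files were used for every value in the report, and the value table served as an alternative only.

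The 135054 gene probes fall into 42575 targets of mostly 3 or 4 probes. For each array the log2 intensities of the probes of a target were summarised by their median, and the 2 arrays of a male were averaged. Of the targets, 38545 were named by the gene identifier in the chip description and 98 by their transcript identifier, against a table of mouse genes of assembly GRCm38.p6 that was used for names only, and 3932 stayed without a name. The named targets belong to 21698 genes, of which 10880 have several targets. Values of gene lists and of their members use the mean over the targets of a gene, and all other gene values are those of 1 target. Background was the 95th percentile of the random-sequence probes of an array (2036 on the kidney chip and 2550 on the others). Where no array of a group exceeded it, the level is called not well above background and the difference is given as at least N-fold, with the group raised to that percentile on each of its arrays. A list member counts as above background in a group if any of its targets exceeds it on an array there. No target was left out for low signal.

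Each tissue was fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, with 4 group means and the pair of slides as a term, over all 24 samples. The contrasts were F1 minus control in CBA/Ca, the same in BALB/c, their mean, their difference (BALB/c minus CBA/Ca), and control BALB/c minus control CBA/Ca. P values were adjusted by Benjamini-Hochberg over all targets, with a threshold of 0.05. Each change is followed, where it matters, by its values within the first and the second pair of slides, each with 3 males per group. A statement such as higher in 6 of 6 F1 males counts males beyond the mean of the control males on the same pair of slides.

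Lists of genes for pathways and for markers of cell types, 38 of them with at least 5 measured members, were tested with camera at its preset correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over 304 pairs of list and contrast for the 8 within-strain contrasts. The circadian clock genes were also tested with fry for a change in either direction. List members were counted after adjustment over all genes and adjusted over the list alone. The genes named are, per within-strain contrast, up to 8 with the highest and 8 with the lowest change among named genes that passed and lay above the median gene of the tissue (4 and 4 for the other contrasts). Where fewer than 5 passed, up to 5 with the smallest p are named. The clock genes, up to 4 members of each further list that passed and up to 10 genes that passed in both strains or in 3 or more contrasts complete the rule. Any other gene is said to have been chosen after its values were seen. The groups, contrasts, lists, this rule and 7 of the 13 alternatives of the closing section were fixed before the data were examined.

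The numbers of the males were checked for pairing across the 2 groups of a strain. In kidney, deviations from the group means correlated across targets between males of the same number with r from 0.33 to 0.64 in CBA/Ca and from 0.34 to 0.50 in BALB/c (6 of 6 pairs over 0.1 in each strain). With the mean of the pair of slides also removed, these ranged from -0.16 to 0.42 and from -0.03 to 0.24. The pairing in kidney therefore came with the shared pair of slides, which is a term of the fit, and the targets behind these correlations are not independent replicates.

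The procedure was tested on simulated data with 200 changed targets among the 42575, in 8 simulations, 1 per tissue and strain. It recovered 2.99 to 28.4% of targets changed by 0.5 on the log2 scale, 58.2 to 89.6% of those changed by 1 and 95.5 to 100% of those changed by 2, and called 3 to 12 unchanged targets. The simulated noise was independent between targets and held no outlying sample, so these numbers do not bound false calls in the real data. There, random regroupings of the same males called up to 132 targets in liver of BALB/c. Arrays were read with data.table (version 1.17.8) and with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of each value.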

Results

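Gene expression was measured in kidney, brain, liver and spleen of male mice of 2 inbred strains, CBA/Ca and BALB/c. In each strain, sons of males that had received 1 Gy of X-rays were set against control males, with 6 males per group and 96 tissue samples in all. Each sample was read on 2 arrays, and each tissue was spread over 2 pairs of slides with 3 males of every group on each pair. The 2 arrays of a male correlated across targets with a median r of 0.979 in kidney, 0.984 in brain, 0.988 in liver and 0.988 in spleen, where targets are not independent replicates. The share of targets brighter than the 95th percentile of random probes ranged from 41.3 to 67.7% of the targets of an array in kidney, 43.1 to 70.4% in brain, 53.9 to 60.4% in liver and 60.6 to 69.3% in spleen. The number of arrays limits the precision of each value. Changes are on the log2 scale with their standard error (SE), F1 minus control, for 6 males against 6, and are followed by the values within the first and the second pair of slides where these are given. The comparisons ask whether offspring of an irradiated father differ from controls in each tissue and whether the strains differ in this.

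In kidney of CBA/Ca males, genes of the circadian clock shifted in opposite directions. Arntl (Bmal1), the core activator of the clock, rose by 2.09 ± 0.28 (2.70 and 1.49 within the slide pairs, limma adjusted p = 0.0019), and its partner Npas2 rose by 2.02 ± 0.36 (2.47 and 1.56, adjusted p = 0.0274). Genes that this activator drives fell. Ciart, a repressor of the clock, fell by 2.63 ± 0.32 (-3.07 and -2.19, adjusted p = 5.4e-04). The transcription factor Dbp fell by 1.89 ± 0.26 (-2.37 and -1.42, adjusted p = 0.0019), and Per2 fell by 1.79 ± 0.20 (-2.01 and -1.56, adjusted p = 2.4e-04). Each of these changes was present in 6 of 6 F1 males. All 3 targets of Arntl and both of Dbp passed, as did 1 of the 2 of Npas2.

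Of the 13 measured genes that clock activators drive through E-box or D-box elements, all 13 lay below control in kidney of CBA/Ca F1 males, with a median of -0.72 (-0.88 and -0.67). In this group 5 fell over all genes tested and 11 when adjusted over the list alone, among them Usp2, a clock-driven deubiquitinase (-0.82 ± 0.15), and Tef, a transcription factor related to Dbp (-0.53 ± 0.10). The 6 genes that peak with Bmal1 had a median of 0.97 (1.34 and 0.89), and 4 of them passed when adjusted over the list alone, including Cry1 (0.63) and Nfil3 (1.31 ± 0.35). Both lists passed with camera at the preset correlation (adjusted p = 1.3e-20 and 2.0e-07) and with an estimated correlation (adjusted p = 0.0157 for each). Over all 24 clock genes, 16 passed when adjusted over the list alone, and fry gave an adjusted p of 2.5e-08 for change in either direction. That test asks whether members change, not whether they change more than other genes.

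Outside the clock lists, kidney of CBA/Ca F1 males had higher Ikzf1, the lymphoid transcription factor Ikaros (1.34 ± 0.19, limma adjusted p = 0.0028). Avpr1a, a vasopressin receptor (0.92 ± 0.16, adjusted p = 0.0230), and Ipmk, an inositol phosphate kinase (0.75 ± 0.13, adjusted p = 0.0259), were higher as well. Clec2h, a C-type lectin (1.01 ± 0.19), Ypel2 (0.93 ± 0.16) and Rhobtb1 (0.79 ± 0.13) were also higher with limma adjusted p from 0.0182 to 0.0458. Cyp27b1, the kidney enzyme that activates vitamin D, fell by 1.54 ± 0.29 (-1.25 and -1.83, adjusted p = 0.0409). Mcm10, a DNA replication factor, fell by 1.46 ± 0.20 (adjusted p = 0.0019, 2 of 3 targets), and the chemokine Cxcl12 fell too (-0.56 ± 0.10, adjusted p = 0.0299). Each was on the stated side in 6 of 6 F1 males. Only 1 of 4 targets of Ikzf1 passed, the others lying as low as 0.07. H2aw, a histone gene outside the rule and chosen after its values were seen, rose by 1.29 ± 0.24 (limma adjusted p = 0.0429, controls above background on 4 of 12 arrays).

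In all, 22 of 42575 targets passed in kidney of CBA/Ca with limma, 11 up and 11 down, covering 16 named genes, against 3291 at unadjusted p under 0.05. No list of genes outside the clock passed with the estimated correlation. At the preset one, targets of p53, the transcription factor that answers DNA damage, had a median of 0.24 (0.05 and 0.28 within the slide pairs, camera adjusted p = 0.0112, adjusted p = 0.0604 with an estimated correlation) with 18 of 25 above control. No member passed, and their values went both ways, as in Ddb2 (-0.31), Tnfrsf10b (0.35), Sesn1 (0.33) and Aen (0.32). Fatty acid synthesis had a median of 0.20 (adjusted p = 0.0113 and 0.500 with an estimated correlation), with Acaca at 0.70 and Elovl6 at 0.98, and cholesterol synthesis one of 0.09 (adjusted p = 0.0177 and 0.284), with Idi1 at 0.89 and Mvd at -0.37. The count of 22 was 34 among the brighter targets alone, 7 with the first array of each male, 8 without the slide term and 67 with sample weights.

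In kidney of BALB/c males no target passed with limma, against 5962 at unadjusted p under 0.05. The smallest adjusted p, 0.0810, belonged to Cdkn1a, the p53-driven inhibitor of the cell cycle (1.31 ± 0.22), to Gnrh1, the gonadotropin-releasing hormone gene (-1.49 ± 0.26), and to Gm14685 (0.77 ± 0.13). Slpi, a protease inhibitor of mucosal surfaces (1.40 ± 0.25, adjusted p = 0.132), and the antibody segment Igkv4-86 (1.40 ± 0.27, adjusted p = 0.136) followed, each on its side in 6 of 6 F1 males. The other target of Cdkn1a was at 0.66 and that of Slpi at 0.33. Of 12 control arrays, 3 were above background for Slpi, 2 for Igkv4-86 and 4 for Gm14685, and for Gnrh1 4 of 12 F1 arrays were. Among clock genes, 5 passed when adjusted over the list alone: Arntl (1.19 ± 0.28), Npas2 (1.38 ± 0.34), Per2 (-0.65 ± 0.20), Clock (-1.10 ± 0.39) and Rora (-0.92 ± 0.31), with adjusted p of 0.196 or more over all genes. The output genes had a median of -0.10 (-0.14 and -0.09, camera adjusted p = 0.0976), and Dbp was at -0.14 ± 0.27. That median was 0.0017 when probes were averaged and -0.21, which passed, with sample weights.

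Several lists passed in kidney of BALB/c at the preset correlation and none with an estimated one. Chromatin and DNA methylation genes had a median of -0.28 (camera adjusted p = 7.5e-04, adjusted p = 0.507 with an estimated correlation), with Suz12, of the Polycomb complex, at -1.11 and Tet2 at -1.05. Heat shock genes had a median of -0.32 (adjusted p = 0.0043 and 0.143), with Hsph1 at -0.78 and Chordc1 at -1.06. Double-strand break repair (-0.14, adjusted p = 0.0157 and 0.649, with Brca2 at -0.43 and Atm at -0.48) and cell cycle genes (-0.11, adjusted p = 0.0215 and 0.755, with Top2a at -0.74 and Mki67 at -0.92, above background on 1 and 3 of 12 F1 arrays) lay lower. Markers of T and NK cells were above control in 11 of 11 members, with a median of 0.25 (adjusted p = 0.0102 and 0.500, with 7 of 11 above background in both groups, Cd8a at 0.54 and Lck at 0.57). Markers of adipose tissue, another tissue than kidney, had a median of 0.73 (0.96 and 0.48 within the slide pairs, adjusted p = 0.0226 and 0.760), with Plin1 at 1.41 and Cfd at 1.13. The 4 Y-linked genes examined, a comparison chosen after their values were seen, had a mean -0.60 from control (-0.52 and -0.68 within the slide pairs). All 4 lay lower (exact permutation p = 0.0455, two-sided, 8 tests, adjusted p = 0.364). In CBA/Ca kidney their mean was 0.34 from control with 0 of 4 lower (-0.10 and 0.78, exact permutation p = 0.396). The SD of Ddx3y over 24 males was 1.19 in kidney and 0.16 to 0.21 in the other tissues. The limma count of 0 became 4 when probes were averaged and 14 with sample weights.

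Over both strains, kidney gave 67 targets with limma, 52 up and 15 down, of which 46 are named and cover 41 genes, against 3382 at unadjusted p under 0.05. Arntl (1.65 ± 0.23, adjusted p = 0.0024), Npas2 (1.70 ± 0.25, adjusted p = 0.0039) and Ikzf1 (1.05 ± 0.14, adjusted p = 9.5e-04) rose, and Ciart (-1.60 ± 0.23), Per2 (-1.22 ± 0.14), Dbp (-1.01 ± 0.19) and the acetyltransferase-like gene Nat8f3 (-1.04 ± 0.16) fell with adjusted p from 4.1e-04 to 0.0227. Igha, the constant region of IgA, rose by 1.68 ± 0.30 (1.93 and 1.43, adjusted p = 0.0180), although its 4 targets ranged from 0.11 to 1.71 and the highest was above background on 1 of 12 BALB/c control arrays. Chosen after their values were seen, 5 variable segments of antibody genes, such as Igkv4-68 (1.06 ± 0.19) and Ighv2-4 (1.23 ± 0.25), both above background on 1 of 12 BALB/c control arrays, rose too, as did Cdkn1a (0.90 ± 0.16, 0.95 and 0.85 within the slide pairs, adjusted p = 0.0174). The list of B and plasma cells had a median of 0.13 and did not pass (camera adjusted p = 0.0992).

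The p53 targets had a median of 0.09 over both strains in kidney, with 17 of 25 above control, and passed at the preset correlation (camera adjusted p = 0.0107) and with an estimated one (adjusted p = 0.0476). The clock output genes had a median of -0.40 (adjusted p = 1.6e-18 and 0.0236 with an estimated correlation) and the Bmal1-phase genes one of 0.61 (adjusted p = 8.5e-06 and 0.0253). Further lists passed at the preset correlation alone: T and NK cells (0.17, adjusted p = 2.4e-04 and 0.193 with an estimated correlation), fatty acid synthesis (0.15, adjusted p = 1.9e-04 and 0.162), cholesterol synthesis (0.15, adjusted p = 0.0023 and 0.0722), adipose tissue (0.30, adjusted p = 0.0335 and 0.783), cell cycle (-0.17, adjusted p = 2.4e-04 and 0.473) and heat shock genes (-0.14, adjusted p = 0.0107 and 0.131). No target differed between the strains in its F1 change with limma (6391 at unadjusted p under 0.05, smallest adjusted p = 0.320). The output genes differed by 0.75 between the strains (camera adjusted p = 1.3e-05, adjusted p = 0.441 with an estimated correlation), and 10 of them passed when adjusted over the list alone. The count of 67 was 14 with the first array, 23 without the slide term, 36 without slide 1 and 155 with sample weights.

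**Figure D1:**
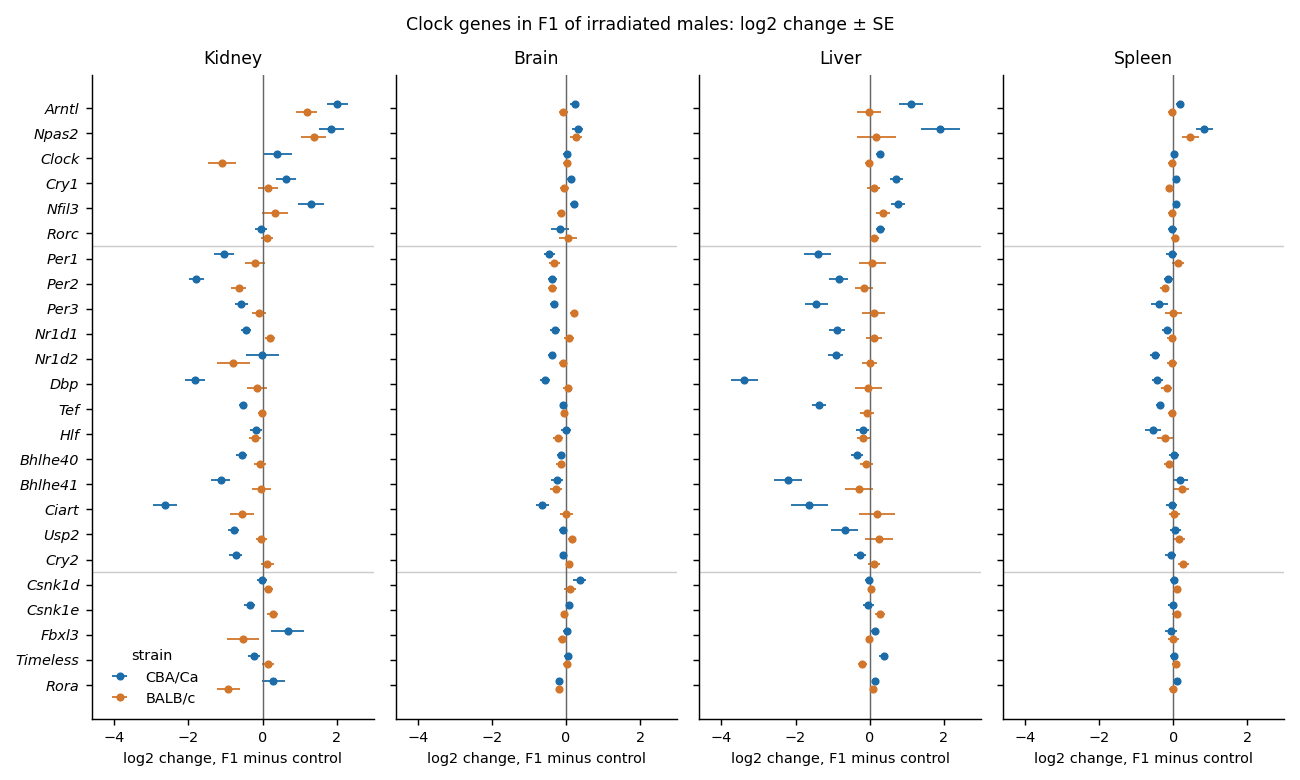
Log2 change (F1 minus control, ± SE, 6 males per group) of 24 circadian clock genes in 4 tissues, CBA/Ca in blue and BALB/c in orange, with grey lines between the 6 Bmal1-phase, 13 output and 5 other genes. In CBA/Ca the median of the output genes was -0.72 in kidney, -0.31 in brain, -0.91 in liver and -0.13 in spleen.

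In brain of CBA/Ca F1 males the clock output genes were lower as a group, by a smaller amount than in kidney. Their median was -0.31 (-0.31 and -0.25 within the slide pairs), 12 of 13 lay below control, and the list passed with camera at the preset correlation (adjusted p = 1.4e-11) and with an estimated one (adjusted p = 0.0014). When adjusted over the list alone, 6 passed: Dbp (-0.57 ± 0.13), Ciart (-0.64 ± 0.17), Per1 (-0.45 ± 0.15), Nr1d2, a nuclear receptor that represses Bmal1 (-0.38 ± 0.10), Per2 (-0.37 ± 0.12) and Per3 (-0.33 ± 0.10). Of these, Dbp, Ciart, Nr1d2 and Per2 were lower in 6 of 6 F1 males, and Per1 and Per3 in 5 of 6. Over all genes none passed (limma adjusted p of 0.911 or more). The Bmal1-phase genes had a median of 0.17 (camera adjusted p = 0.0910), and all 24 clock genes one of -0.09 (adjusted p = 0.0027 and 0.0259 with an estimated correlation).

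No target passed with limma in brain of CBA/Ca (1929 at unadjusted p under 0.05). The genes with the smallest p were dim: Stpg4, the interleukin-22-like Iltifb, the nucleoplasmin Npm2, the antibody segment Ighv1-36 and Parp11, with adjusted p of 0.968 or more. Each was not well above background in the controls, the F1 males or both, and no fold can be given for them. Targets of Stpg4, Npm2 and Parp11 disagreed in sign. Neutrophil markers had a median of -0.33 (-0.51 and -0.15, camera adjusted p = 1.5e-04, adjusted p = 0.207 with an estimated correlation), with Ngp at -0.997 and S100a9 at -0.69. Above background were 4 of 12 F1 arrays for Ngp, 7 for S100a9 and 0 for Mpo. Ribosomal protein genes had a median of 0.08 (adjusted p = 0.0112 and 0.669 with an estimated correlation, with Rps15 at 0.20), and markers of cholangiocytes and stellate cells one of -0.19 (adjusted p = 0.0112 and 0.284, with Des at -0.57 and Epcam at -0.52, above background on 3 and 1 of 12 F1 arrays).

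In brain of BALB/c F1 males, immediate early genes, which neurons switch on with activity, were lower as a group at the preset correlation. Their median was -0.30 (-0.26 and -0.42), 16 of 20 lay below control and the camera adjusted p was 8.0e-06, but 0.511 with an estimated correlation. The members with the smallest p were Nr4a3 (-0.65), the phosphatase Dusp1 (-0.73), the synaptic gene Arc (-1.15) and Junb (-0.67), none of which passed. Ribosomal protein genes lay below control in 20 of 22 members (median -0.12, adjusted p = 1.3e-04 and 0.476 with an estimated correlation, with Rpl13 at -0.20), and erythroid genes had a median of -0.13 (adjusted p = 0.0333 and 0.500, with 6 of 11 members above background in both groups, Slc4a1 at -0.52 and on 3 of 12 F1 arrays, and Hba-a1 at -0.39). The clock output genes had a median of -0.05 (-0.15 and 0.04, adjusted p = 0.304), and no clock gene passed when adjusted over the list alone.

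No target passed with limma in brain of BALB/c (3500 at unadjusted p under 0.05). Ptgr2, a prostaglandin reductase, was lowest (-2.97 ± 0.47, -1.67 and -4.26 within the slide pairs, adjusted p = 0.0616), with 3 of its 4 targets of the same sign. Next came Prss27, a serine protease (-1.05 ± 0.19), Rfx6 and the vomeronasal receptor Vmn2r122, all with adjusted p = 0.168. Rfx6 was not well above background in the controls (F1 above it on 3 of 12 arrays) and Vmn2r122 in both groups, so no fold is given for them. Over both strains no target passed (3607 at unadjusted p under 0.05), and none differed between the strains with limma (1626). Over both strains the output genes had a median of -0.14 (camera adjusted p = 9.3e-07 and 0.0186 with an estimated correlation) and the immediate early genes one of -0.22 (adjusted p = 2.5e-05 and 0.473). Chromatin genes (-0.06, adjusted p = 0.0424 and 0.394) and neutrophil markers (-0.14, adjusted p = 0.0335 and 0.473, with 2 of 9 members above background in every group) passed at the preset correlation. The output genes differed by 0.17 between the strains (adjusted p = 0.0015 and 0.314 with an estimated correlation). The count of 0 in BALB/c was 2 without the second array of F1 male 2, whose arrays correlated least (r = 0.916), 2 when probes were averaged and 1 among brighter targets or with sample weights.

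In liver of CBA/Ca F1 males, Dbp fell by 3.98 ± 0.43 (-4.51 and -3.45 within the slide pairs, limma adjusted p = 6.7e-05), to a level above background on 5 of 12 arrays. Its relative Tef fell by 1.44 ± 0.19 (-1.85 and -1.03, adjusted p = 0.0012), and Nr1d2 fell too (-1.08 ± 0.21, adjusted p = 0.0369, 1 of 3 targets). Bhlhe41, a repressor of the clock, was not well above background in the F1 males and fell to a level at least 1.80-fold lower than control (adjusted p = 0.0183). Both targets of Dbp and both of Tef passed, and each of these changes was present in 6 of 6 F1 males. Per3, outside the rule and chosen after its values were seen, was not well above background in the F1 males and fell to a level at least 2.36-fold lower than control (adjusted p = 0.0056).

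All 13 clock output genes lay below control in liver of CBA/Ca F1 males, with a median of -0.91 (-1.45 and -0.68; -0.86 for the 10 above background in both groups), and 9 passed when adjusted over the list alone, including Ciart (-1.63), Nr1d1 (-0.88) and Per2 (-0.83). All 6 Bmal1-phase genes lay above control, with a median of 0.75 (0.91 and 0.53), and all 6 passed when adjusted over the list alone, including Npas2 (1.91 ± 0.52), Arntl (1.12 ± 0.32), Nfil3 (0.77) and Cry1 (0.72 ± 0.18). Both lists passed with camera at the preset correlation (adjusted p = 1.3e-20 and 1.8e-08) and with an estimated one (adjusted p = 0.0394 and 0.0157). Over all 24 clock genes 16 passed when adjusted over the list alone, Timeless (0.37) being the other that was higher, and fry gave an adjusted p of 3.5e-07 for change in either direction.

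Outside the clock lists, liver of CBA/Ca F1 males had higher Ntrk2, the receptor of the growth factor BDNF (2.04 ± 0.21, 2.05 and 2.03 within the slide pairs, limma adjusted p = 4.4e-05). Clpx, a subunit of the mitochondrial ClpXP protease (1.81 ± 0.23, 1.62 and 2.01, adjusted p = 6.7e-04), and Loxl4, a lysyl oxidase of the extracellular matrix (2.07 ± 0.41, 2.71 and 1.44, adjusted p = 0.0462), were higher as well. The third target of Ntrk2 was at -0.13, and the targets of Clpx ranged from 0.21 to 1.81. Nat8f3 (1.13 ± 0.22, 1 of 4 targets), 1700010I14Rik (1.11 ± 0.21), Gfod1 (0.81 ± 0.15), Ccng2, an atypical cyclin (0.81 ± 0.14), and Arl4a (0.72 ± 0.14) rose too, with adjusted p from 0.0229 to 0.0450. Lower were Cyp2a4, a steroid hydroxylase (-1.44 ± 0.27, adjusted p = 0.0328, 4 of 4 targets), Asns, asparagine synthetase (-1.34 ± 0.24, adjusted p = 0.0198), Gnat1, a transducin subunit (-1.05 ± 0.17, adjusted p = 0.0123), and Mtss1 (-1.04 ± 0.19, adjusted p = 0.0286). Each was on its side in 6 of 6 F1 males.

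In all, 44 targets passed in liver of CBA/Ca with limma, 22 up and 22 down, covering 34 named genes, against 3391 at unadjusted p under 0.05. Exocrine pancreas genes, which liver does not normally make, differed by a median of -1.61 (-0.13 and -2.94 within the slide pairs, camera adjusted p = 1.3e-04, adjusted p = 0.746 with an estimated correlation), with 1 of 13 members above background in both groups. Ctrb1 and Cpa1 were above it on 2 of 12 control arrays and 0 of 12 F1 arrays. Their mean log2 intensity was 13.42 in control male 4 and no more than 5.32 in any other liver of the group. An exact permutation test of the group difference in that mean gave p = 0.0065 (two-sided, 8 tests, adjusted p = 0.0519). Every split puts control male 4 in 1 group, so this p value does not measure the size of the difference. Chromatin genes had a median of 0.07 (camera adjusted p = 0.0486, adjusted p = 0.545 with an estimated correlation), with Dnmt3b, a DNA methyltransferase, at 0.88, and acute phase genes one of -0.14 (adjusted p = 0.0448 and 0.545), with Saa1 at -0.48. The count of 44 was 22 without control male 4, 17 with the first array, 24 without the slide term, 25 with male number as block, 67 with sample weights, 73 among brighter targets and 74 when probes were averaged.

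**Figure D2:**
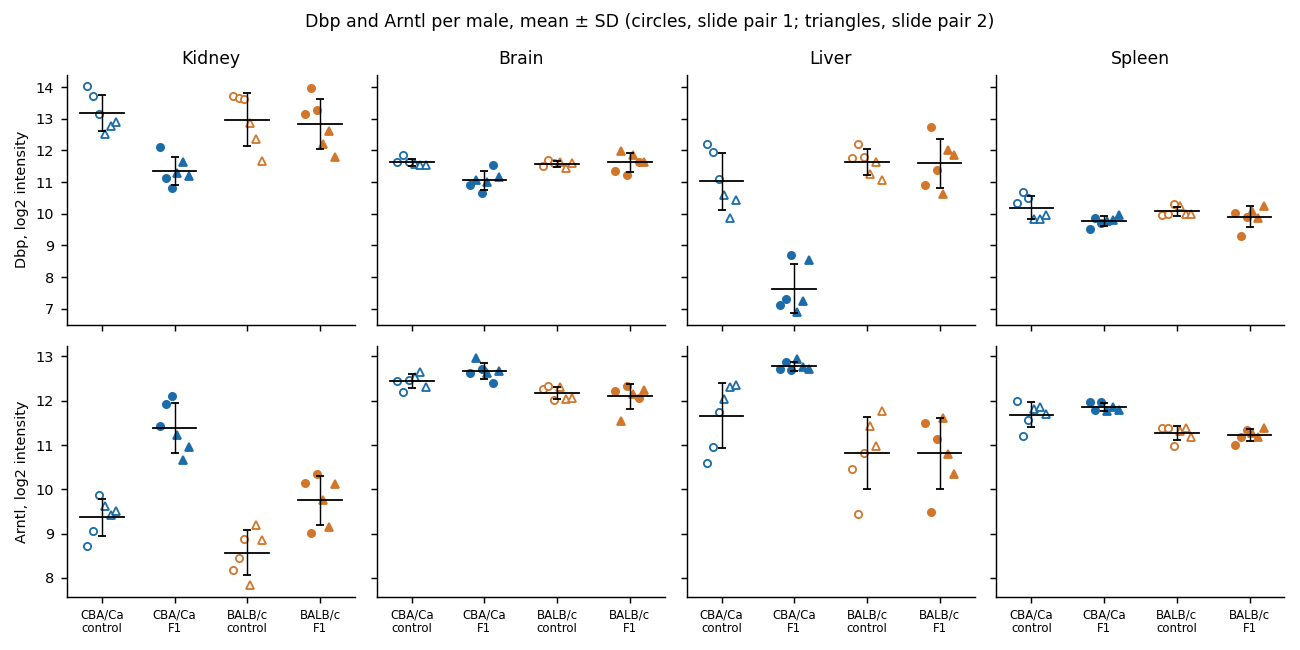
Log2 intensity of Dbp and Arntl in each male (mean ± SD per group, 6 males), open symbols for control and filled for F1, circles for the first and triangles for the second pair of slides. In liver the mean of the 2 targets of Dbp changed by -3.38 on the log2 scale in CBA/Ca F1 males and was at -0.03 in BALB/c.

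In liver of BALB/c males no target passed with limma (2484 at unadjusted p under 0.05, smallest adjusted p = 0.223). That value was shared by Ntrk2 (1.08 ± 0.21), Iqcb1 (1.12 ± 0.22, controls above background on 3 of 12 arrays), Egfl8 (-0.65 ± 0.13, F1 above it on 3 of 12), the glutamate receptor Grm8 and 1700029H14Rik. Grm8 was not well above background in the controls (F1 above it on 7 of 12 arrays), nor was 1700029H14Rik in any group, so no fold is given for them. Targets of Iqcb1, 1700029H14Rik and Egfl8 disagreed in sign. Clock genes showed no shift that passed: the output genes had a median of 0.01 (camera adjusted p = 0.957), Arntl was at -0.01 and Dbp at -0.03, and no member passed when adjusted over the list alone. Lists that passed at the preset correlation alone were neurons (-0.36, adjusted p = 0.0038 and 0.545 with an estimated correlation, with 5 of 12 members above background in both groups and a median of -0.09 for these), cell cycle (-0.13, adjusted p = 0.0131 and 0.775, with Mki67 at -0.81 and Top2a at -0.68) and T and NK cells (-0.21, adjusted p = 0.0157 and 0.469, with Cd3g at -0.40). Of the neuron genes, Snap25 and Stmn2 were not well above background in the F1 males.

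Dbp was the gene whose F1 change in liver differed between the strains with limma, by 3.96 ± 0.60 (4.33 and 3.59 within the slide pairs, adjusted p = 0.0480, against 3080 targets at unadjusted p under 0.05). Its other target differed by 2.74. Asns (1.77 ± 0.33), Eml2 (0.97), Pla2g12a (0.86) and Ddias, not well above background in CBA/Ca controls, came next and did not pass (adjusted p = 0.117). The output genes differed by 0.99, with 13 of 13 above 0 (camera adjusted p = 5.3e-12, adjusted p = 0.314 with an estimated correlation). Over both strains 7 targets of 5 genes passed with limma (2951 at unadjusted p under 0.05): Ntrk2 (1.51 ± 0.14, 1.53 and 1.48, adjusted p = 2.0e-05), Nat8f3 (0.98 ± 0.16), Clpx (0.98 ± 0.16), Dbp (-2.00 ± 0.30, adjusted p = 0.0103) and, chosen after its values were seen, Grm8 (adjusted p = 0.0093), with BALB/c controls not well above background. In the same contrast the output genes had a median of -0.49 (camera adjusted p = 3.8e-13, adjusted p = 0.0835 with an estimated correlation), the Bmal1-phase genes one of 0.48 (adjusted p = 0.0253 with an estimated correlation), neurons one of -0.20 (adjusted p = 0.0078 and 0.487, 3 of 12 members above background in every group) and pancreas genes one of -0.79 (adjusted p = 0.0056 and 0.834, 1 of 13). The pancreas value came with 1 sample, CBA/Ca control male 4, at 13.42 against 5.26 to 5.32 in the others of his group. The difference for Dbp no longer passed without control male 4, without the slide term, with quantile normalization, with male number as block, with sample weights or when probes were averaged (0 targets each), and the count of 7 was 4 without that male and 3 with the first array.

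In spleen, exocrine pancreas genes were bright in most males: their mean log2 intensity ranged from 5.69 to 14.71, with a median of 13.25 and 20 of 24 samples over 8. In kidney the range was 5.72 to 6.52, and in brain 5.60 to 5.96. The level did not follow the groups in a way that passed. F1 minus control was 0.60 in CBA/Ca (exact permutation p = 0.751, two-sided, adjusted p = 0.751) and -1.10 in BALB/c (exact permutation p = 0.528, adjusted p = 0.680). The median change of these genes turned sign between the slide pairs, from 3.70 to -2.28 in CBA/Ca and from -4.31 to 2.17 in BALB/c.

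**Figure D3:**
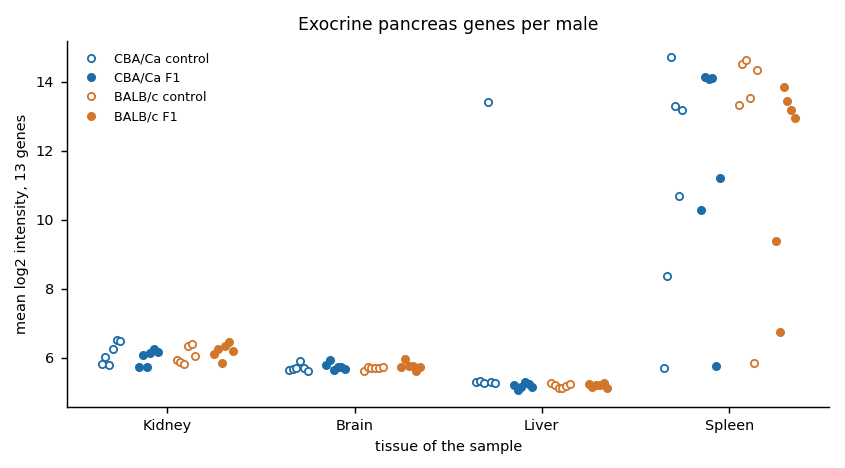
Mean log2 intensity of 13 exocrine pancreas genes in each male, by group and tissue. In spleen 20 of 24 samples exceed 8, and in liver 1 of 24 does.

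In spleen of CBA/Ca F1 males the clock genes stood out little. The output genes had a median of -0.13 (-0.35 and 0.02 within the slide pairs) with 10 of 13 below control, and passed with camera at the preset correlation (adjusted p = 0.0010) but not with an estimated one (adjusted p = 0.469). When adjusted over the list alone, 3 clock genes passed: Npas2 (0.84 ± 0.23), Nr1d2 (-0.49 ± 0.13) and Tef (-0.35 ± 0.11), each in 6 of 6 F1 males. The Bmal1-phase genes had a median of 0.08 (0.17 and 0.02, adjusted p = 0.0226 and 0.184 with an estimated correlation). Neutrophil markers had a median of -0.46 (0.29 and -1.20, adjusted p = 0.0038 and 0.746 with an estimated correlation), with the elastase Elane at -0.90. Cell cycle genes (-0.10, 0.02 and -0.22, adjusted p = 0.0047 and 0.812, with Kif11 at -0.30), erythroid genes (-0.16, 0.04 and -0.43, adjusted p = 0.0131 and 0.746, with Klf1 at -0.41) and heat shock genes (-0.11, adjusted p = 0.0112 and 0.669, with Hsph1 at -0.40) passed at the preset correlation as well. The medians of neutrophil, cell cycle and erythroid genes changed sign between the slide pairs.

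No target passed with limma in spleen of CBA/Ca (1456 at unadjusted p under 0.05). The smallest adjusted p, 0.405, belonged to Vezt, an adherens junction gene (0.71 ± 0.13), and Star, which brings cholesterol into mitochondria (-0.49 ± 0.09), ahead of Il20rb, Ceacam14 and Olfr707, all not well above background in the controls. In spleen of BALB/c males 2 targets passed with limma, both up (2129 at unadjusted p under 0.05). Nudt18, a nucleotide hydrolase, rose to a level at least 1.18-fold above control (adjusted p = 4.5e-04), the control being not well above background and the F1 above it on 11 of 12 arrays. Its other target was at 0.09 and did not pass. Ceacam14, a cell adhesion gene, passed too (adjusted p = 0.0037), but no fold is given, with the control not well above background, the F1 above it on 4 of 12 arrays and the other target at -0.19. Both were higher in 6 of 6 F1 males. Tarm1 (0.83 ± 0.17) did not pass, nor did Pde7b and Adap1, which were not well above background in either group.

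The clock genes did not pass in spleen of BALB/c, with a median of -0.03 for the output genes (camera adjusted p = 0.930). Heat shock genes had a median of -0.14 (adjusted p = 3.3e-04 and 0.500 with an estimated correlation), and 3 passed when adjusted over the list alone; Hspa1a was at -0.57 and Dnajb1 at -0.35. Macrophage markers lay above control in 12 of 12 members (0.10, adjusted p = 0.0177 and 0.500, with C1qb at 0.19). Antioxidant genes (0.08, adjusted p = 0.0131 and 0.469, with Hmox1 at 0.39), interferon-response genes (0.13, adjusted p = 0.0333 and 0.746, with Mx1 at 0.32) and adipose markers (-0.34, adjusted p = 0.0333 and 0.651, with 4 of 9 members above background in both groups) passed at the preset correlation too. Adipoq was at -1.33 and above background on 5 of 12 F1 arrays. Over both strains 4 targets passed with limma (2222 at unadjusted p under 0.05): Ceacam14 (adjusted p = 8.8e-04), Nudt18 (adjusted p = 0.0341), Pde7b (adjusted p = 0.0327) and Il20rb (adjusted p = 0.0485), all up. Each was not well above background in BALB/c controls, and Pde7b in every group, so no fold is given. The other target was at -0.18 for Ceacam14, -0.05 for Nudt18 and 0.21 for Il20rb. Vezt (0.52, BALB/c controls above background on 1 of 12 arrays) did not pass (adjusted p = 0.0674). Heat shock genes had a median of -0.09 over both strains (camera adjusted p = 8.5e-06, adjusted p = 0.246 with an estimated correlation), and the clock output genes one of -0.10 (adjusted p = 0.0335 and 0.527). No target differed between the strains in its F1 change with limma (1316 at unadjusted p under 0.05), and the output genes differed by 0.18 (adjusted p = 0.0359 and 0.599 with an estimated correlation). The counts of 2 and 4 were each 0 among the brighter targets and with the first array of each male.

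The 2 strains themselves differed in many genes, in each tissue and in both pairs of slides. Control BALB/c minus control CBA/Ca gave 2117 targets in kidney, 2568 in brain, 5187 in liver and 7932 in spleen with limma. C1s1, a complement protease, was higher in BALB/c by 4.85 ± 0.14 in liver, 4.35 ± 0.09 in spleen and 4.39 ± 0.25 in kidney, where CBA/Ca controls were above background on 1 of 12 arrays. Genes of the major histocompatibility complex differed both ways, with H2-D1 (4.71 ± 0.49 in kidney and 2.88 ± 0.29 in brain), H2-K1 (2.90 ± 0.20 in brain, 6 of 6 targets) and H2-Q8 (4.45 in spleen) higher in BALB/c and H2-Q1 lower (-6.15 ± 0.23 in liver, where BALB/c controls were above background on 1 of 12 arrays, 3 of 6 targets). The 6 targets of H2-Q1 in liver ranged from -6.15 to 0.88. AI506816 was lower in BALB/c (-4.89 in kidney, -3.99 in brain and -3.71 in spleen). A single target stood alone for several genes, among them Agt, angiotensinogen (-5.10 ± 0.41 in kidney, 1 of 2 targets), Ptgr2 (-4.74 ± 0.31 in kidney, 1 of 4 targets), Wtap (-3.39 in brain, 1 of 4) and Marf1 (-3.19 in brain, 1 of 5).

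Further strain differences in kidney were Gcnt1, a glycosyltransferase, at least 40.3-fold higher in BALB/c with CBA/Ca not well above background, Gm13272 (4.45, CBA/Ca above background on 2 of 12 arrays) and Gm5376, at least 12.3-fold lower with BALB/c not well above background. In brain, 1700030C10Rik (3.31) and the synaptic scaffold gene Lin7c (2.79 ± 0.14) were higher in BALB/c and Paip1 lower (-3.01). In liver, Cox6b2 (4.96 ± 0.14), Serpina5 (at least 8.26-fold) and the protease Ctse (5.23, other target -1.67) were higher. Cox6b2 and Ctse were above background on 1 of 12 CBA/Ca control arrays. Lower in BALB/c liver were Cyp46a1, a cholesterol hydroxylase (-5.99 ± 0.22, both targets), Serpina1e (-4.01) and Gon4l (at least 8.62-fold). In spleen, antibody genes led, with Ighv5-16 at least 68.8-fold and Ighg1, the IgG1 constant region, at least 46.2-fold lower in BALB/c, Ighv3-4 at -6.76 and Ighv9-2 at 3.97 (CBA/Ca above background on 4 of 12 arrays), and Slfn8 was higher (4.51). The 8 targets of Ighg1 disagreed: they ranged from -8.04 to 0.54, and 1 of them passed. For the target given, each gene was on its side in 6 of 6 BALB/c males, with limma adjusted p of 3.4e-07 or less.

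Among gene lists, cell cycle genes were higher in BALB/c spleen in 24 of 24 members, with 19 passing over all genes (median 0.61, camera adjusted p = 3.3e-13, adjusted p = 0.631 with an estimated correlation). Erythroid genes were also higher there (0.78, adjusted p = 4.3e-05 and 0.631 with an estimated correlation, 9 members passing up), as were double-strand break repair (0.23, adjusted p = 0.0035 and 0.631), interferon-response (0.41, adjusted p = 0.0095 and 0.858) and antioxidant genes (0.14, adjusted p = 0.0337 and 0.631). Markers of B and plasma cells (-0.26, adjusted p = 4.7e-04 and 0.631) and of T and NK cells (-0.24, adjusted p = 0.0227 and 0.631) were lower in BALB/c spleen. Chosen after the values were seen, the pancreas score averaged 12.70 in BALB/c and 10.99 in CBA/Ca control spleens (exact permutation p = 0.366, two-sided, 4 tests, adjusted p = 0.732). In the livers it averaged 5.18 and 6.65 (exact permutation p = 0.0022, adjusted p = 0.0087). Male 4 of the CBA/Ca controls raised the second mean, at 13.42 against 5.26 to 5.32 in the others of his group. Every split puts that male in 1 group, so the p value does not measure a strain difference of this size. In BALB/c liver, genes of fatty acid synthesis were lower (-0.49, adjusted p = 8.9e-05 and 0.631, 8 passing down), and macrophage markers (0.34, adjusted p = 8.9e-05 and 0.631, 6 passing up) and interferon-response genes (0.35, adjusted p = 0.0095 and 0.953) higher. Double-strand break repair genes were higher in BALB/c kidney (0.15, adjusted p = 0.0478 and 0.953 with an estimated correlation). The kidney count of 2117 was 772 without the slide term, the brain count of 2568 was 1649 among brighter targets and 4125 with sample weights, and with the first array the counts of 5187 and 7932 were 2723 and 3717.

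Across tissues, Dbp was the 1 gene that passed in the same direction in 2 of the 8 comparisons within a strain, falling in kidney and liver of CBA/Ca. No gene passed in the same direction in both strains of a tissue. Changes over all targets correlated little between kidney and liver of CBA/Ca (r = 0.12 across targets, which are not independent replicates). Both targets of Dbp were the ones that passed in both tissues. With independent targets and tissues 0.0057 would be expected, but 2 targets of 1 gene are not independent. Between the strains the changes correlated with r = -0.30 in kidney, 0.20 in brain, 0.02 in liver and 0.0029 in spleen, and in brain 5 of 100 random splits gave as high a value. In BALB/c the changes in brain correlated with those in liver at r = 0.17 and those in kidney with liver at 0.15, each above the highest of the other splits (0.12 and 0.13). Kidney with brain (0.14) and brain with spleen (0.13) were each reached by 2 of 100 splits, the real one included. Liver with spleen (0.12) was reached by 6 and kidney with spleen (0.07) by 20. These counts were not adjusted over the correlations examined. The splits were drawn for each tissue apart and do not keep males of 1 number together across tissues. They cannot separate a shared F1 change from what the tissues of 1 male may share.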

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

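The tests of explanations in this part, and the counts of random splits, were chosen after the results they measure were seen.

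The series' value table holds columns named BALB/c control and CBA/Ca F1 that follow the arrays of another group. All 48 of these columns matched the same-numbered male of the other of the 2 groups, in all 4 tissues, which is what an exchange of these columns when the table was made would give. The opposite explanation, exchanged array files, is argued against by 200 targets per tissue that set the strains apart: on a scale from CBA/Ca control (0) to BALB/c F1 (1), the highest array sample named CBA/Ca F1 lay at 0.115 and their mean was 0.0170, whereas the value-table columns of that name averaged 0.960. A candidate explanation is therefore an exchange of columns in the table, as a hypothesis found and tested on the same data, and it would turn a contrast of F1 and control within a strain into a contrast of strains. No biological explanation was tested.

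Clock output genes were lower in CBA/Ca F1 males, with medians of -0.72 in kidney, -0.31 in brain and -0.91 in liver. The separate normalization of the arrays of kidney slide 1 is argued against by a median of -0.75 without that slide. Within the slide pairs of kidney, brain and liver, 6 of 6 medians lay below 0, so the shift was present in each pair. Each pair held 3 males of every group, so a pair difference common to all groups could not give the shift. The medians therefore do not test it. Output and Bmal1-phase genes had medians on opposite sides of 0 in 4 of 4 tissues, which a different hour of tissue collection for the CBA/Ca F1 males would also give. The labels do not give the hour, so this may be the source of the pattern and cannot be told apart from a change of the clock itself. Whether the genes that changed outside the clock lists follow the hour was not tested. The labels do not say whether males of 1 number are the same animal in every tissue. The tissues may therefore not be independent of each other. The difference that the design names, irradiation of the father, stays open as an untested explanation.

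Liver of CBA/Ca control male 4 carried exocrine pancreas genes at a mean log2 intensity of 13.42, with a gap to the nearest of the other 5 males of 0.992 of the group's range. Ctrb1 stood at 15.02 against 6.92 in the highest other liver, Cpb1 at 14.70 against 5.33 and Cel at 14.61 against 4.98, and 12 of 13 measured members were more than 3 log2 units above every other liver on both arrays. A candidate explanation is pancreas tissue carried into this sample, as a hypothesis. A fault of 1 hybridisation is argued against by the lower of its 2 arrays, 8.01 above the highest array of another liver, and another tissue in place of liver by a hepatocyte score -0.027 from the mean of the other 23. No biological explanation was tested.

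Of 170 groups of 6 males examined, 9 held a male far from the others by the Dixon test (4 of 48 list scores and 5 of 122 groups of a named gene). Chance flags about 1 in 20 groups. Pancreas scores had a gap of 0.851 of the range in spleen of BALB/c controls (male 5 at 5.85 against 13.32 to 14.63) and 0.668 in brain of CBA/Ca controls (male 4 at 5.90 against 5.61 to 5.71). The Bmal1-phase score of spleen CBA/Ca F1 had one of 0.667 (male 3 at 9.44 against 9.53 to 9.57). Among genes, Ikzf1 had a gap of 0.662 in kidney CBA/Ca F1 (male 3 at 9.40 against 8.46 to 8.78) and Cdkn1a one of 0.670 in kidney BALB/c controls (male 6 at 8.94 against 9.98 to 10.49). Male 1 of the liver CBA/Ca controls was low in 1700010I14Rik (0.657, 8.60 against 9.36 to 9.76) and Arl4a (0.695, 8.83 against 9.14 to 9.28). Olfr707 had a gap of 0.671 in spleen CBA/Ca F1 (male 1 at 5.89 against 6.22 to 6.39).

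The F1 change differed between the strains, BALB/c minus CBA/Ca, for 26 pairs of list and tissue at camera's preset correlation and for 0 with an estimated correlation (adjusted p from 0.314 to 0.853). In kidney these were Bmal1-phase genes (-0.65, adjusted p = 0.0266), clock output genes (0.75, adjusted p = 1.3e-05), double-strand break repair (-0.19, adjusted p = 0.0197), chromatin (-0.26, adjusted p = 0.0029) and inflammation (0.41, adjusted p = 0.0266). In brain they were clock output (0.17, adjusted p = 0.0015), immediate early (-0.13, adjusted p = 0.0227), ribosomal protein (-0.18, adjusted p = 2.6e-08), neutrophil (0.38, adjusted p = 0.0085) and erythroid genes (-0.16, adjusted p = 0.0266). In liver they were Bmal1-phase (-0.51, adjusted p = 0.0015), clock output (0.99, adjusted p = 5.3e-12) and all clock genes (0.29, adjusted p = 0.0266), chromatin (-0.12, adjusted p = 0.0029), inflammation (0.16, adjusted p = 0.0085), T and NK cells (-0.15, adjusted p = 0.0387), neutrophils (0.093, adjusted p = 0.0387) and pancreas (1.60, adjusted p = 0.0097). In spleen they were clock output (0.18, adjusted p = 0.0359), fatty acid synthesis (-0.10, adjusted p = 0.0266), cholangiocytes and stellate cells (-0.16, adjusted p = 0.0135), macrophages (0.11, adjusted p = 0.0266), neutrophils (0.71, adjusted p = 0.0023), erythroid genes (0.26, adjusted p = 0.0387), pancreas (-1.67, adjusted p = 0.0334) and adipose tissue (-0.48, adjusted p = 0.0074). Members above background in every group were 2 of 9 for neutrophils in brain, 1 of 9 for neutrophils and 1 of 13 for pancreas in liver, and 4 of 9 for adipose tissue in spleen. The pancreas difference in liver came with 1 sample, CBA/Ca control male 4, at 13.42 against 5.26 to 5.32 in the others of his group. Dbp in liver differed by 3.96 with limma (adjusted p = 0.0480).

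Other splits of the same males into groups of 6, 100 with the real one, were fitted in the same way. The labels do not give fathers or litters, so the splits treat the 6 males of a group as independent. They cannot address a difference between families. A share of 1 in 100 is the smallest they can give, and the shares were not adjusted over the results examined. No other drawn split reached the counts in kidney CBA/Ca (22, highest other 7) and kidney over both strains (67, highest other 0). Nor did any reach the count in liver CBA/Ca (44, highest other 14). Each of these counts was reached by 1 of 100 splits, the real one. The same holds for the control strains in kidney (2117, highest other 398), brain (2568, highest other 149), liver (5187, highest other 913) and spleen (7932, highest other 5490). It also holds for the size of the clock output median in CBA/Ca kidney (0.72, highest other 0.67), brain (0.31, highest other 0.28) and liver (0.91, highest other 0.87). For the clock medians the highest other split lay close to the real one, and a split that was not drawn may exceed it. Chance cannot be excluded for the counts in liver over both strains (7, highest other 37, reached by 5 splits) and for the liver difference between strains (1, highest other 2, reached by 6). The target of that difference is of Dbp, and the splits count targets without testing the change of Dbp itself. Nor can chance be excluded for the clock median in spleen CBA/Ca (0.13, highest other 0.26, reached by 29) and in BALB/c kidney (0.10, highest other 0.38, by 41), brain (0.05, highest other 0.11, by 27), liver (0.0075, highest other 0.46, by 97) and spleen (0.03, highest other 0.20, by 79).

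Counts of 0 are reached by all 100 splits: kidney BALB/c (highest other 1) and its difference between strains (1), brain CBA/Ca (1), BALB/c (2), over both strains (2) and their difference (1), liver BALB/c (20), and spleen CBA/Ca (4) and its difference between strains (2). A split of liver over both strains that calls 37 targets, and one of liver BALB/c that calls 20, point to a structure of the liver samples, and what it follows was not tested. A first draw of 100 splits gave 132 targets as the highest other in liver BALB/c and 71 in spleen CBA/Ca, which points to such a structure in spleen too. In that draw the real 7 of liver over both strains was reached by 1 split, the real one (highest other 2), so that its standing depends on the draw. The 2 of spleen BALB/c and the 4 of spleen over both strains were each reached by 1 split, the real one, in the draw used above (highest other 1 each). In the first draw they were reached by 2 splits (highest other 2) and by 2 (highest other 14). There, 1 split besides the real one called as many or more.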

How the results depend on the processing

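The alternatives chosen after seeing the data are the mean of the probes, the sample weights, the models without kidney slide 1, without liver CBA/Ca control male 4 and without the second array of brain BALB/c F1 male 2, and the pancreas term in spleen. Of 253 values, 176 stayed the same. For a count this means within 1.5 times, whatever its direction. For a clock output median it means the same sign and the same call with camera, whatever its size. With the value table set aside, the CBA/Ca clock output median ranged from -0.75 to -0.69 in kidney, -0.39 to -0.28 in brain, -0.98 to -0.89 in liver and -0.19 to -0.09 in spleen, and the counts of brain CBA/Ca, liver BALB/c and spleen CBA/Ca stayed at 0. With the pancreas term, 7 of 7 spleen values were the same. Signal over background limits the dim genes: Nudt18, Ceacam14, Pde7b and Il20rb in spleen lie below the median gene. Unless a cause is named, the cause was not tested.

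Camera with an estimated correlation gave 6 pairs of list and contrast in place of 40. With only targets above the median gene, so that fewer were tested, the counts were 34 in kidney CBA/Ca, 73 in liver CBA/Ca, 1 in brain BALB/c, 0 in spleen BALB/c, 0 in spleen over both strains and 1649 for the strains in brain, and the liver BALB/c clock median was -0.049. The first array of each male alone, with 1 array each, gave 7 in kidney CBA/Ca, 14 in kidney over both strains, 17 in liver CBA/Ca, 3 in liver over both strains, 2 for the liver difference between strains, 0 in spleen BALB/c, 0 in spleen over both strains, 1 for the spleen difference, 2723 and 3717 for the control strains in liver and spleen, and -0.0018 for the liver BALB/c clock median.

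The mean of the probes gave 4 in kidney BALB/c, 2 in brain BALB/c, 74 in liver CBA/Ca, 0 for the liver difference, 1 in spleen BALB/c, 0 in spleen over both strains, and clock medians of 0.0017 in kidney BALB/c and -0.0074 in liver BALB/c. Without the slide term the counts were 8 in kidney CBA/Ca, 23 in kidney over both strains, 772 for the kidney strains, 24 in liver CBA/Ca and 0 for the liver difference. Quantile normalization gave 2 in spleen over both strains and 0 for the liver difference. With the replicate block, a pairing by male number in place of the slide pair, the counts were 25 in liver CBA/Ca (24 of them shared with the 44), 0 for the liver difference, 1 in brain over both strains and 1 in spleen over both strains, and the other 24 values were the same.

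Sample weights gave 67 in kidney CBA/Ca, 14 in kidney BALB/c, 155 in kidney over both strains, 3 for the kidney difference, 1 in brain BALB/c, 4125 for the brain strains, 67 in liver CBA/Ca, 0 for the liver difference, and a kidney BALB/c clock median of -0.21 that then passed. Without liver CBA/Ca control male 4, so with 1 sample fewer, the counts were 22 in liver CBA/Ca (all 22 shared), 4 over both strains and 0 for the difference. Without kidney slide 1, with fewer arrays, kidney over both strains gave 36 (32 shared), and without the second array of the brain male BALB/c gave 2.

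In the value table the columns named BALB/c control and CBA/Ca F1 match the arrays of the other of these groups. If they are exchanged, contrasts within a strain compare strains and the contrast of control strains compares CBA/Ca F1 with control. The table gave F1 counts of 2231, 3424 and 4450 in kidney (CBA/Ca, BALB/c, both), 3644, 2831 and 6650 in brain, 6282, 8473 and 11913 in liver, and 9505, 9414 and 15204 in spleen. The control strains gave 20 in kidney, 0 in brain, 74 in liver and 0 in spleen, and the liver difference 0. Clock medians were 0.020 (kidney CBA/Ca), 0.70 (kidney BALB/c), 0.040 (brain CBA/Ca), 0.24 (brain BALB/c), 0.43 (liver CBA/Ca), 1.63 (liver BALB/c, which then passed), 0.093 (spleen CBA/Ca) and 0.44 (spleen BALB/c).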

Other observations

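The comparisons described here were chosen after the values were seen, and none carries a test of an explanation. Clock genes also differed between the pairs of slides within the control groups, which hold 3 males each per pair. In liver of CBA/Ca controls Dbp averaged 11.75 on the first pair and 10.29 on the second, and Arntl 11.10 and 12.23. In liver of BALB/c controls the output genes averaged 10.61 and 10.15, and Arntl 10.25 and 11.40. In kidney, Dbp averaged 13.63 and 12.73 in CBA/Ca controls and 13.67 and 12.29 in BALB/c controls. The kidney arrays were normalized apart, with median intensities of 367.2 on slide 2 of the first pair and 251.8 and 244.1 on the slides of the second. Kidney levels of the 2 pairs, in controls and F1 males alike, are therefore not on a common scale. In the F1 males of CBA/Ca, Dbp averaged 11.36 and 11.37 in kidney and Arntl 11.82 and 10.95, against 9.21 and 9.52 for Arntl in the controls. In liver of these F1 males the output genes averaged 8.69 and 8.68 and Arntl 12.76 and 12.80.

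Several further lists did not pass in any comparison of F1 and control within a strain. Markers of the kidney proximal tubule had their smallest adjusted p in kidney of CBA/Ca (median 0.09, camera adjusted p = 0.0749), xenobiotic metabolism in liver of CBA/Ca (-0.02, adjusted p = 0.162), fatty acid oxidation in liver of CBA/Ca (0.05, adjusted p = 0.213), and glucocorticoid targets in brain of CBA/Ca (-0.06, adjusted p = 0.0910). Base and nucleotide excision and mismatch repair genes had theirs in liver of BALB/c (0.05, adjusted p = 0.0910). Hepatocyte genes had a mean log2 intensity in kidney from 9.22 to 11.94 in 23 males and of 13.08 in BALB/c F1 male 2.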
